A study of Homo sapiens with 4 samples.

How the data were processed

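The samples were 4 total RNA preparations of MKN45 cells, an established line of human gastric adenocarcinoma, each labelled with Cy3 and hybridised to a one-colour Agilent human array. The labels put 2 arrays in the untreated control group and 2 in the group cultured with fucoidan at 1 mg/ml. The replicate numbers came from the sample titles and were used only as names, except in an alternative with the replicate number as a block. The labels do not say that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The length of the treatment is not given in the sources used here.

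The authors deposited 1 file per array from Agilent Feature Extraction 10.7.3.1, extracted with protocol GE1_107_Sep09 for array design 039494 on build hg19 (GRCh37), per the file headers. In the deposited files the processed signal is a fluorescence intensity on a linear scale, made by the authors' extraction within each array by spatial detrending, background subtraction and multiplicative detrending, with surrogate values for spots near background. The deposited files also give mean and local background intensity per spot, and other columns of the deposited files are flags that mark spots as well above background, saturated or outlying. The values of the deposited series table were compared with the processed signal spot by spot and differed by at most 0, so they are the same intensity, neither logged nor centred. No scaling between arrays had been applied. All arrays lay on 1 slide and were read in 1 scan, with the control arrays at positions 1 and 2 and the fucoidan arrays at positions 3 and 4.

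Each array held 62976 spots, of which 58717 were not controls and represented 50599 probes. Spots marked as non-uniform were left out, and population outliers were left out where other spots of the probe remained. Spots of a probe were averaged on the log2 scale, and the 75th percentile of the array was subtracted, so that levels are log2 signal relative to that percentile. A probe entered where it was well above background on both arrays of at least 1 group, and a gene was represented by its entering probe with the highest mean. Probes were named through a table of RefSeq genes. The accession named 28174 probes, a current symbol 2618 and an older symbol 620, while 19187 kept the name in the file. In all, 27402 probes of 20627 genes or transcripts were tested, 14963 of them with a current symbol. Probe coordinates are those of the files on hg19. On arrays the signal over background and the number of arrays limit the precision, and 56.9% to 59.0% of the non-control spots were well above background.

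Fucoidan was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Besides this fit with 1 prior variance for all genes, an intensity trend, in which the prior variance follows the signal of a gene, was among the alternatives. SE values are those of the fit without the trend, also where an adjusted p with the trend stands beside them. Genes with both fucoidan arrays at least 2-fold above or below both control arrays were counted without a p. The limma function camera, with a preset correlation of 0.01, compared each gene list with all other genes. Of 39 lists, 38 had the 5 tested members required, and the list of endothelial markers, with 3, was left out. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Those that combine the intensity trend with other settings were added after the data were seen, as was the list test on trend statistics. Camera with the intensity trend had been fixed before and gave the same list values as that test.

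The rule named the 10 genes with the largest change in each direction among genes past the threshold, well above background on all 4 arrays and with both fucoidan arrays beyond both control arrays, passing over systematic names. Where fewer than 10 passed, the 10 largest with an unadjusted p below 0.05 were given as values with no claim of change, which applied in both directions. The rule also named up to 3 genes past the threshold and detected in 1 group only, per direction, up to 4 members of each list past its threshold in the direction of the majority and up to 2 in the other, and MAP3K5, DBF4, CDC7, MET, MYC, CCND1, CDKN1A and MKI67 whatever their values. Some genes that the rule names are not reported here. A fold for a transcript not well above background in 1 group was bounded by the detection floor of that group's arrays and written as at least that fold.

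The test was checked on simulated data with 200 changed genes among 20627 and 20 draws. The spread of each gene was drawn from the variances that the intensity trend fitted to these arrays, and genes were drawn independently. The data thus follow the model of the trend, which favours its recovery. The fit with 1 prior variance recovered 0% of genes changed 1.25-fold, 1.5% at 1.5-fold, 53.3% at 2-fold and 82.1% at 4-fold. With the intensity trend the shares were 33.1%, 62.2%, 79.9% and 94.7%. False calls made up 3.18% and 5.13% of calls. A shift of 0.08 in the mitosis list was called in 100% of draws. These data hold no correlation between genes, so the draws cannot test the list call under such correlation.

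Alternatives covered normexp background correction with an offset of 50, quantile and median scaling, the series table, the filters on dim probes, a signal floor, the probes of a gene, the replicate block, the variance model, the thresholds, treat at 1.2-fold, each array left out in turn, camera with an estimated correlation and fry. Preparation used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Intervals around medians over genes are 95% bootstrap intervals from 2000 draws, and genes are not independent replicates. No treatment of the raw images was repeated.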

Results

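Gene expression was measured in MKN45 cells, a line of human gastric adenocarcinoma, with and without fucoidan, a sulfated polysaccharide whose main sugar is fucose. There were 2 arrays of untreated cells and 2 arrays of cells cultured with fucoidan at 1 mg/ml. On each array 56.9% to 59.0% of the non-control spots were well above background, and 0 spots were saturated. Across genes, which are not independent replicates, the log2 signals correlated at 0.997 between the control arrays, at 0.997 between the fucoidan arrays, and at 0.996 across the groups. The control arrays lay at positions 1 and 2 of the slide and the fucoidan arrays at positions 3 and 4, so position and treatment cannot be told apart.

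The comparison addressed which genes could mediate the effects of fucoidan on these cells, and the series title names their growth. Transcripts of SPRR3 and SPRR1B, small proline-rich proteins of the cornified envelope of squamous epithelia, lay 2.13-fold and 2.30-fold lower with fucoidan, but did not pass the test (adjusted p = 0.123 and 0.138) except under the alternatives given with their values. Histone genes, genes of mitosis and DNA replication, ribosomal protein genes, and genes of the extracellular matrix, TGF-beta and NF-kB responses lay lower as groups, except that the ribosomal median turned with quantile normalization, whereas genes of cholesterol and fatty acid synthesis lay higher. None of these list calls held with an estimated correlation (adjusted p = 0.62 for 8 lists and 0.73 for the matrix genes with an estimated correlation). That version of camera rests on the 2 residual degrees of freedom of the fit, so it had little power. It cannot tell whether correlation between genes explains the calls. The estimate lay below the preset 0.01 for ribosomal proteins (−0.0146), YAP and TGF-beta targets (−0.0246) and fatty acid synthesis (0.00035). Their camera p still rose, as from 0.000285 to 0.0480 for ribosomal proteins. For the other lists named here the estimate lay above the preset. The median differences were at most 0.16 in size on the log2 scale. The transcripts of both kinases or kinase regulators that share the name ASK, MAP3K5 and DBF4, did not pass the test (adjusted p = 0.988 and 0.603).

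Of 20627 genes tested with limma, 0 were higher and 1 was lower at an adjusted p below 0.05, while 963 were higher and 1244 lower at an unadjusted p below 0.05, where 1031 in all would be expected with no effect. In 20.01% of genes both fucoidan arrays lay above, and in 25.3% below, both control arrays, against 16.7% by chance in each direction. That balance of unadjusted counts moved to 993 higher and 635 lower with median scaling and to 1184 higher and 1054 lower with quantile normalization. Median scaling shifts all genes of an array alike, and it took the median difference over all genes from −0.0091 to 0.028. Control replicate 1 had the highest median signal, 34.7, and the lowest 75th percentile, 483.6, so the choice between these scalings moves that array. Without control replicate 1 the balance also leaned higher, with a median difference over all genes of −0.00014 against −0.0091. Without any other single array it leaned lower. With an intensity trend in the variance, limma called 31 genes higher and 135 lower, by a median of 1.27-fold and 1.29-fold, of which 2 and 14 were at least 2-fold apart. Among these, 2 higher and 11 lower genes were detected in 1 group only, so that their differences rest on values near background in the other group. In fits added after the data were seen, the trend gave 72 and 138 without control replicate 1 and 58 and 351 without control replicate 2. It gave 34 and 76 without fucoidan replicate 1 and 63 and 158 without fucoidan replicate 2. The fewest calls shared with the 166 were 69, without fucoidan replicate 1. Under other scalings the trend gave 87 and 170 with median scaling and 21 and 69 with quantile normalization. Only 77 of the calls with median scaling were among the 166, and 90 of those with quantile normalization. The 1 gene called without the trend was the transcript XLOC_013479 (chromosome 20, 21511302 to 21511361), which was detected on both control arrays at −2.23 ± 0.14 (SD, n = 2) and on neither fucoidan array, and was at least 8.49-fold lower (adjusted p = 0.0246). Its adjusted p was 0.309 without the filter on dim probes, 0.0512 with a signal floor and 0.141 with the replicate block. Without control replicate 1, fucoidan replicate 1 or fucoidan replicate 2 its call was lost, at differences of −5.21, −5.35 and −5.26. Normexp correction brought its difference from −5.31 to −1.53. That correction adds an offset of 50 to each signal, which is above the highest median signal of 34.7. It therefore shrinks the differences of dim genes by construction. In both fucoidan arrays 9 genes were at least 2-fold above and 23 at least 2-fold below both control arrays, of which 3, namely CA5A, SPRR1B and SPRR3, were well above background on all arrays. The other splits of the 4 arrays into pairs gave 1 and 2 such genes in all, against these 32. A difference between the groups cancels in those splits, which put a control and a fucoidan array on each side, so low counts were likely in advance. Between the arrays of a single pair, 236 genes lay at least 2-fold apart in control and 114 with fucoidan. The series text gives 496 genes up and 774 down of 20278 sequences, with no threshold in the sources used here.

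**Figure D1:**
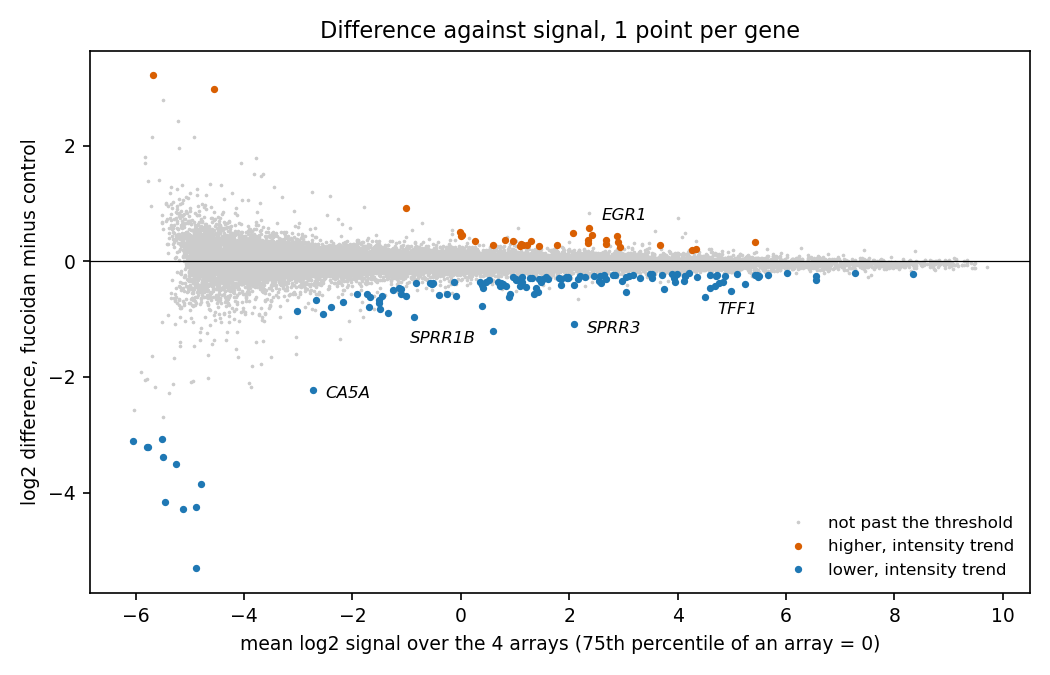
Difference between groups (log2, fucoidan minus control) against mean log2 signal over the 4 arrays, 1 point per gene; coloured points are the 31 higher and 135 lower genes called with the intensity trend. SPRR1B and SPRR3 lie at −1.20 and −1.09 at moderate signal, and the widest scatter lies among dim genes.

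Among the brighter transcripts with the largest lower values, SPRR3 (chromosome 1, 152976230 to 152976289) went from 2.64 ± 0.01 in control to 1.55 ± 0.02 with fucoidan (SD, n = 2), a difference of −1.09 ± 0.04 (SE; adjusted p = 0.123, and 6.85e-05 with the intensity trend). SPRR1B (chromosome 1, 153005304 to 153005363) went from 1.201 ± 0.03 to −0.0033 ± 0.05, a difference of −1.20 ± 0.05 (adjusted p = 0.138, and 0.000126 with the trend). CA5A, a mitochondrial carbonic anhydrase, differed by −2.23 ± 0.41 (SE) with a larger spread between the fucoidan arrays (adjusted p = 0.0218 with the trend). FAM25A at −0.96, ZBED2 at −0.89 and NUTM2A at −0.79 also passed with the trend (adjusted p = 0.00274, 0.0106 and 0.0237), although another probe of NUTM2A gave −0.072 and the mean over its probes −0.43. The values of GOLGA7B at −1.40, ESRRG, the estrogen-related receptor gamma, at −0.91, GMFG at −0.81 and LYZL1 at −0.80 passed neither fit. GOLGA7B stood at −0.88 without control replicate 2 and LYZL1 at −0.53 without control replicate 1. Of the 10 genes with the largest higher values only FAM177B, at 0.92 ± 0.13 (SE), passed with the trend (adjusted p = 0.0118). PFN3, a testis profilin, stood at 1.06 ± 0.06 (adjusted p = 0.246, and 0.0550 with the trend). The others, CCDC196, MAP3K14-AS1, BST1, GXYLT2, SLC52A1, ENPP5, MAPT-IT1 and AGPAT4-IT1, had values from 0.87 down to 0.59 and passed neither fit. AGPAT4-IT1 stood at 0.36 without fucoidan replicate 1. Another probe of MAPT-IT1 gave 0.19 and the mean over its probes 0.39. Without the trend none of these 20 genes passed on the processed signal scaled to the 75th percentile, a fit that recovered 53.3% of genes at 2-fold in simulated data. SPRR1B, SPRR3 and FAM25A passed without it after normexp correction (adjusted p = 0.0046, 0.0030 and 0.0344). With median scaling these as well as CA5A, ZBED2, NUTM2A, PFN3, FAM177B, CCDC196, MAP3K14-AS1 and ENPP5 passed, at an adjusted p of 0.0460 at most. Normexp correction, however, made the values of 15 of the 20 genes over 1.5 times smaller, such as 0.30 for PFN3, 0.16 for GXYLT2 and MAPT-IT1, −1.10 for CA5A and −0.54 for GOLGA7B. Its offset shrinks the differences of dim genes by construction, and how much of the fall it accounts for was not tested.

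**Figure D2:**
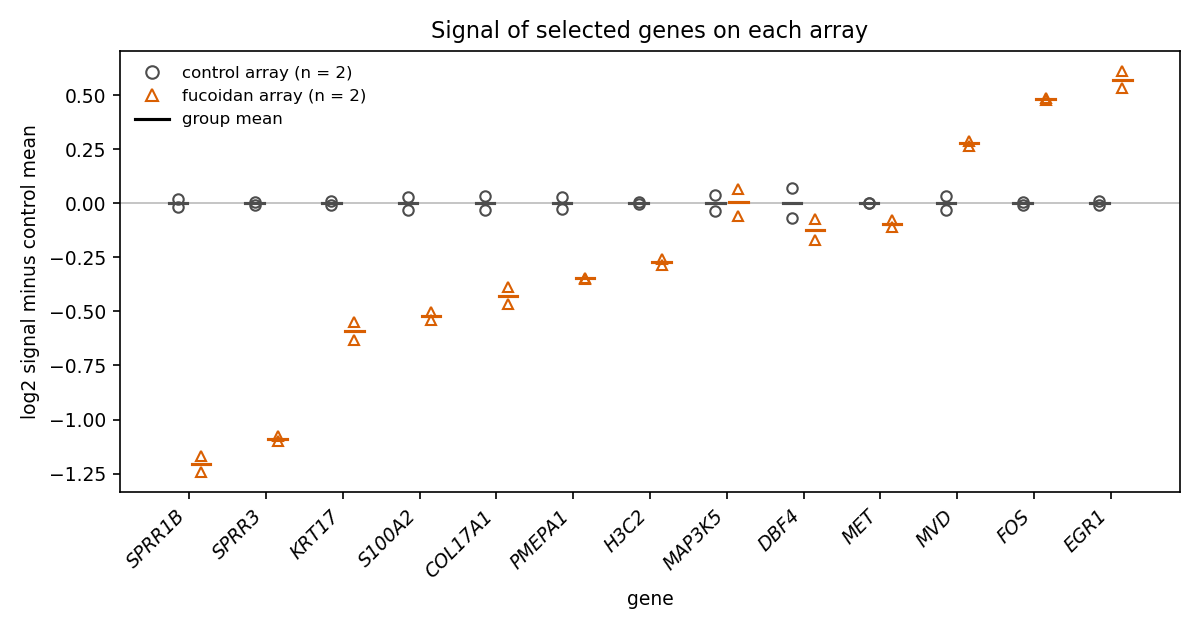
Log2 signal of selected genes on each array relative to the control mean; circles are control arrays, triangles fucoidan arrays and bars group means (n = 2 each). The fucoidan arrays lie below both control arrays for SPRR1B through H3C2, overlap them for MAP3K5, and lie above them for MVD, FOS and EGR1.

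Genes of the cell cycle and of chromatin lay lower as groups. Of 25 histone genes 24 were lower, by a median of −0.16, and in 20 both fucoidan arrays lay below both control arrays, which holds for 25.3% of all genes tested (camera, adjusted p = 1.83e-07). Of 48 genes of mitosis and G2 phase 42 were lower, by a median of −0.073, 31 of them without overlap between the groups (adjusted p = 7.87e-05). Of 52 genes of DNA replication and S phase 46 were lower, by a median of −0.055, 29 of them without overlap between the groups (adjusted p = 0.000989). With an estimated correlation none of these 3 calls held (adjusted p = 0.62 for each list with an estimated correlation), and without control replicate 2 the adjusted p was 0.0618 for mitosis and 0.0839 for DNA replication. With median scaling the median was −0.036 for mitosis (adjusted p = 0.0499) and −0.018 for DNA replication (adjusted p = 0.137). No member passed on its own over all genes or adjusted over the list alone, except that H3C2, a replication-dependent histone H3 gene (chromosome 6, 26031922 to 26031981), passed with the intensity trend at −0.27 ± 0.04 (SE; adjusted p = 0.0164). Other histone genes had values of −0.28 for H2AC11, −0.24 for H2AC4 and −0.21 for H2AC6, whose other probes gave 0.065 and −0.078 and whose mean over probes was −0.075. In the mitosis list NCAPG, a condensin subunit, stood at −0.23, NUSAP1 at −0.15, KIF2C at −0.14 and HMMR at −0.13, against 0.099 for ECT2 and 0.10 for CKS2. Without control replicate 1 NCAPG stood at −0.15 and ECT2 at 0.065. In the replication list MCM4, part of the replicative helicase, stood at −0.29, CCNE2, a cyclin E gene, at −0.22, CHAF1A at −0.20 and E2F2 at −0.15, against 0.046 for UNG and 0.081 for POLE2. Other probes of CCNE2 and CHAF1A gave 0.051 and 0.086, and the means over their probes were −0.084 and −0.056. MKI67, a marker of cycling cells, differed by −0.031 ± 0.10 (SE, adjusted p = 0.920), a sign that turned with median scaling.

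Lipid synthesis genes lay higher as groups. Of 26 genes of cholesterol synthesis and SREBP2 targets 22 were higher, by a median of 0.068, and 13 had both fucoidan arrays above both control arrays (adjusted p = 7.87e-05; adjusted p = 0.62 with an estimated correlation). The median was 0.13 without fucoidan replicate 1, 0.12 with normexp and quantile normalization and 0.11 with median scaling. MVD, the mevalonate diphosphate decarboxylase, stood at 0.28 ± 0.05 (SE; adjusted p = 0.0493 with the intensity trend), TM7SF2 at 0.24, LSS, the lanosterol synthase, at 0.21 (0.35 with the mean over probes) and HMGCS1, the cytosolic HMG-CoA synthase, at 0.19. EBP at −0.036 and NSDHL at −0.016 lay on the other side, and both were above 0 with quantile normalization and with median scaling. Of 29 genes of fatty acid synthesis and lipid droplets 19 were higher, by a median of 0.082, 16 of them without overlap between the groups (adjusted p = 0.0270; adjusted p = 0.62 with an estimated correlation and 0.386 with median scaling), and with any 1 array left out its adjusted p lay between 0.0864 and 0.158. The median was 0.023 with the mean over probes and 0.038 with each probe on its own, where the list did not pass (adjusted p = 0.0909 and 0.0858), nor did it with the replicate block (adjusted p = 0.0684). ACSL1, an acyl-CoA synthetase, stood at 0.26, DGAT2 at 0.15 and FADS2 at 0.13, against −1.03 ± 0.36 (SE) for ANGPTL4, an inhibitor of lipoprotein lipase. ANGPTL4 stood at −1.08 and −2.02 on the control arrays, and its difference was −0.56 without control replicate 1 and −0.66 with normexp correction. Apart from MVD with the intensity trend, no member of these lists passed over all genes or adjusted over the list alone.

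Adhesion and signalling genes lay lower in 3 lists. Of 31 genes of the extracellular matrix and integrins 24 were lower, by a median of −0.087, 18 of them without overlap between the groups (adjusted p = 0.000713; adjusted p = 0.73 with an estimated correlation). The median of the matrix genes was −0.051 without fucoidan replicate 2, −0.050 with median scaling and −0.039 with normexp and quantile normalization. COL17A1, a collagen of epithelial hemidesmosomes, stood at −0.43 ± 0.06 (SE; adjusted p = 0.0156 with the intensity trend), TIMP1, an inhibitor of metalloproteinases, at −0.24 (adjusted p = 0.0432 with the trend) and ITGB6 at −0.30 (−0.19 with normexp correction), against 0.059 for CD44 and 0.13 for VTN. Of 22 YAP and TGF-beta targets 18 were lower, by a median of −0.087, 14 of them without overlap between the groups (adjusted p = 0.0118; adjusted p = 0.62 with an estimated correlation and 0.137 with median scaling). With median scaling their median was −0.050, and with normexp and quantile normalization −0.049. PMEPA1, a TGF-beta target, stood at −0.35 ± 0.05 (SE; adjusted p = 0.0106 with the trend), BAMBI at −0.23, ID1 at −0.18 and AJUBA at −0.15, whereas CCN2, a YAP target near background, stood at 0.27, or 0.097 to 0.44 with single arrays left out, and LTBP3 at 0.11. Of 37 NF-kB and inflammatory cytokine genes 27 were lower, by a median of −0.071, 18 of them without overlap between the groups (adjusted p = 0.0270; adjusted p = 0.62 with an estimated correlation and 0.122 with median scaling). Their median was −0.034 with median scaling and −0.044 with quantile normalization. The NF-kB list passed camera neither without the filter on dim probes (adjusted p = 0.340) nor with the replicate block (adjusted p = 0.0588). The chemokine genes CCL5 and CCL2 stood at −0.61 and −0.58 and CSF2 at −0.33, all of them dim, PI3, the gene of the elastase inhibitor elafin, at −0.27 (adjusted p = 0.0383 with the trend), LIF at 0.19 and NFKB2 at 0.090. Normexp correction, whose offset shrinks the differences of dim genes by construction, brought CCL5, CCL2 and CSF2 to −0.20, −0.11 and −0.072. Adjusted over the list alone, 0 members of these lists passed. With arrays left out the adjusted p was 0.1004 for matrix genes without fucoidan replicate 2, 0.107 and 0.0864 for YAP and TGF-beta targets without control replicate 2 and fucoidan replicate 2, and 0.0532 to 0.158 for NF-kB genes without any 1 array.

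Ribosomal protein genes were the most uniform group. Of 48 members 47 were lower, by a median of −0.050, and 32 had both fucoidan arrays below both control arrays (adjusted p = 0.00181; adjusted p = 0.62 with an estimated correlation), but the median turned to 0.00026 with quantile normalization (adjusted p = 0.760) and to 0.0030 with normexp and quantile normalization (adjusted p = 0.806). With median scaling the median was −0.013 (adjusted p = 0.349), and without control replicate 2 the adjusted p was 0.158. RPS13 stood at −0.13, RPS24 and RPL6 at −0.10 and RPS19 at 0.0037. Another, dim probe of RPS24 gave 0.14 and another probe of RPS19 −0.040. Over all genes and adjusted over the list alone, 0 members passed.

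**Figure D3:**
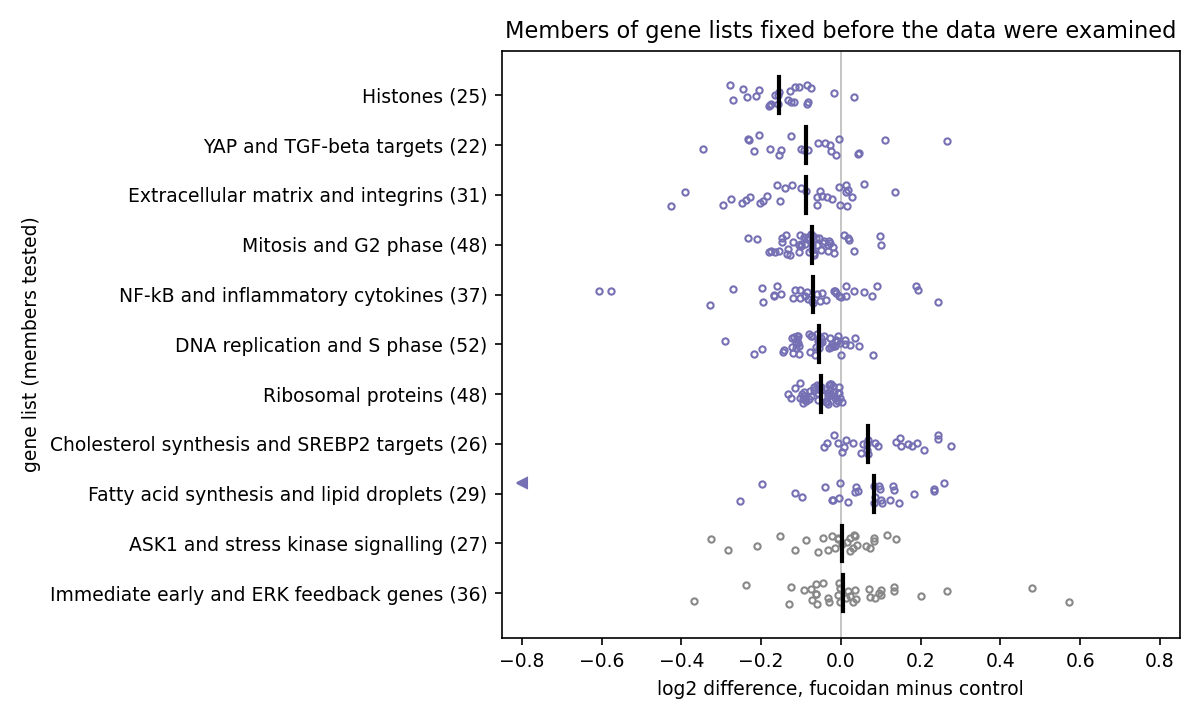
Log2 difference (fucoidan minus control) of each tested member of 11 gene lists, with the number of members in brackets and a bar at the median; the purple lists passed the list test and the grey ones did not, and the triangle at the left edge is ANGPTL4, beyond the axis at −1.03. The medians run from −0.16 for histones to 0.082 for fatty acid synthesis, and the ribosomal protein median, −0.050 here, lies above 0 with quantile normalization.

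The series title names a fall in phosphorylated ASK1, which it describes as a kinase of the cell cycle, and arrays measure transcripts, not phosphorylation. MAP3K5, the gene of apoptosis signal-regulating kinase 1 (chromosome 6, 136878349 to 136878408), stood at −0.35 ± 0.05 in control and −0.35 ± 0.09 with fucoidan (SD, n = 2), a difference of 0.0037 ± 0.07 (SE, adjusted p = 0.988), while a dimmer probe gave 0.45. DBF4, the activator of the S phase kinase CDC7 and also known as ASK (chromosome 7, 87516653 to 87516712), stood at 0.71 ± 0.10 and 0.59 ± 0.07, a difference of −0.12 ± 0.08 (adjusted p = 0.603), which ranged from −0.19 to −0.052 with single arrays left out, and a dim probe gave −0.26. CDC7 itself stood at −0.058 ± 0.05 (SE, adjusted p = 0.671). Of 27 genes of ASK1 and stress kinase signalling 14 were higher and 13 lower, with a median of 0.0037 and a mean of −0.022. Camera gave the direction as down (adjusted p = 0.957). The receptor gene MET differed by −0.096 ± 0.04 (SE, adjusted p = 0.521), MYC by 0.13 ± 0.04 (adjusted p = 0.460), CCND1 by 0.030 ± 0.04 (adjusted p = 0.816) and CDKN1A, the gene of the inhibitor p21, by −0.082 ± 0.06 (adjusted p = 0.626). CCND1 stood at 0.013 without control replicate 1 and at 0.047 without control replicate 2, where CDKN1A stood at −0.042.

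Of the 38 lists tested, the other 29 did not pass, with adjusted p from 0.161 to 0.957. With camera and the intensity trend, a setting fixed before the data were examined, 2 lists were higher and 9 lower. The list test on trend statistics, added after the data were seen, gave the same values. Glycolysis and hypoxia (adjusted p = 0.0389) and epithelial junction and keratin genes (adjusted p = 0.0490) passed besides the 7 lower lists. In the fit without the trend these 2 lists had an adjusted p = 0.83 and an adjusted p = 0.62 with an estimated correlation. Among stress and survival lists the adjusted p was 0.218 for p53 targets and cyclin-dependent kinase inhibitors, 0.239 for apoptosis regulators, of which 26 of 34 were lower, 0.620 for the unfolded protein response, 0.913 for NRF2 targets, 0.596 for heat shock proteins and 0.161 for metallothioneins. Among metabolic lists it was 0.161 for glycolysis and hypoxia, with 27 of 36 lower, 0.888 for oxidative phosphorylation, 0.913 for LXR targets, 0.872 for iron handling, 0.295 for xenobiotic metabolism and 0.610 for ribosome biogenesis. For surface and sugar genes it was 0.591 for heparan sulfate genes, 0.483 for fucose metabolism, 0.380 for scavenger receptors and endocytosis, and 0.922 for lysosome and autophagy. Signalling lists gave 0.561 for immediate early genes, 0.872 for receptor tyrosine kinases, 0.341 for WNT targets, 0.239 for Notch targets, 0.516 for interferon-stimulated genes and 0.913 for antigen presentation. Lineage lists gave 0.239 for gastric and intestinal genes, 0.190 for epithelial junction and keratin genes and 0.922 for epithelial-mesenchymal transition. Markers of other cell types gave 0.343 for fibroblasts, 0.295 for leukocytes and 0.203 for erythroid and serum genes. The camera direction was up where median and mean lay below 0 for antigen presentation and iron handling, and up with a median above 0 and a mean below 0 for fucose metabolism and interferon-stimulated genes.

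Single members of these lists passed with the intensity trend, and the genes in this account were chosen after their values were seen. The immediate early transcription factors EGR1 and FOS were higher, at 0.57 ± 0.05 and 0.48 ± 0.04 (SE; adjusted p = 0.00225 and 0.00254 with the trend), and both passed adjusted over the list alone (adjusted p = 0.0107 each). In the gastric and intestinal list, which did not pass (adjusted p = 0.239), TFF1, SPINK4, REG4 and ANXA10 were lower, at −0.62 ± 0.04, −0.36, −0.25 and −0.22 (SE; adjusted p = 0.000390, 0.00839, 0.0276 and 0.0431 with the trend), TFF1 and SPINK4 also adjusted over the list alone. CAV1, the gene of caveolin 1, at −0.53 and DKK1, a WNT antagonist, at −0.48 (adjusted p = 0.00162 each with the trend) and OASL at −0.42 (adjusted p = 0.00914) passed both ways. HAS3, a hyaluronan synthase, at −0.39 (adjusted p = 0.0218; −0.14 with the mean over probes) and GMDS, the enzyme that starts GDP-fucose synthesis, at 0.34 (adjusted p = 0.0143) passed with the trend, whereas HAS2, at −0.38, passed only adjusted over the list alone (adjusted p = 0.0478). In the xenobiotic list ALDH1A1 at 0.24, ABCC2 at −0.39 and CYP3A7 at −0.29 passed both ways and CYP1A1, at −0.41, only adjusted over the list alone. AREG at −0.28, NUPR1 at −0.36, CEACAM1 at −0.22 and CEACAM6 at −0.25 passed with the trend alone. In the other tested lists 0 members passed adjusted over the list alone.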

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

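The alternatives were planned except the intensity trend with any array left out or under other scalings, the list test on trend statistics and the count of list members with the trend, tests that were chosen after the result was seen. Camera with the intensity trend was planned and gave the same list values as the list test on trend statistics. Gene calls varied between settings: against 0 higher and 1 lower, limma called 31 and 135 with the intensity trend, 72 and 138 with the trend and without control replicate 1, 3 and 20 with normexp and either the 75th percentile or quantile normalization, and 39 and 46 with median scaling. All 23 normexp calls, and 27 of those with median scaling, were among the 166 trend calls with the same sign. The lower count was 0 without the filter on dim probes, with detection on all 4 arrays, with a signal floor, with the replicate numbers as a block and at an adjusted p below 0.01. Leaving out single arrays gave 0 to 1 higher and 0 to 9 lower genes, the highest without control replicate 2. The cause was not tested for the scaling and block settings, nor for the gene calls with normexp. The normexp offset shrinks the differences of dim genes by construction. The trend changes the prior degrees of freedom from 1.69 to 6.03. The smaller or larger sets of genes and the stricter threshold act by construction.

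The counts of genes at least 2-fold apart on every array, 9 and 23, were 0 and 3 with normexp under both scalings and with detection on all 4 arrays, 2 and 10 with a signal floor, 103 and 90 without the filter, 34 and 52 at 1.5-fold, and 41 and 65 between group means. They ranged over 28 to 57 and 42 to 111 with single arrays left out. An array left out removes comparisons that the rule asks for, so these counts could not fall, by construction. The signal over background limits the counts: 29 of the 32 genes were not well above background on any array of 1 group. The normexp offset shrinks the differences of such genes by construction. Lists higher and lower, 2 and 7, were 1 and 3 with median scaling and 0 and 0 with camera and an estimated correlation. That version rests on 2 residual degrees of freedom, so its lack of calls cannot tell whether correlation between genes matters. With fry they were 0 and 3, of which ribosomal proteins alone belonged to the 7, the others being the heparan sulfate and epithelial junction lists. Higher lists numbered 1 with the mean over probes, with each probe on its own and with the replicate block, and 1 with any array left out, where lower lists fell to 2 without control replicate 2 and to 4 without fucoidan replicate 2 and otherwise reached 6. The cause was not tested.

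Of 20 alternatives the histone and cholesterol lists passed in 18 each, mitosis and matrix in 17 each, DNA replication in 16, ribosomal proteins and YAP and TGF-beta targets in 15 each, NF-kB in 11 and fatty acid synthesis in 10. These are not separate checks. The series table repeats the main values, so its passes were fixed in advance. Camera with the trend and the list test on trend statistics gave the same adjusted p and are both counted. Over 114 genes, 1928 of 2048 values kept their direction and side of the threshold, 96 passed newly, 7 no longer passed and 17 changed sign, none of the last past the threshold. The series table and the settings of the block, the variance model, treat and the stricter threshold keep each difference as in the main fit. In those settings a sign could not change. With quantile normalization EBP was 0.0129 and NSDHL 0.0080, and with median scaling EBP was 0.0014, NSDHL 0.0206 and MKI67 0.0055. NSDHL was 0.0044 with normexp and quantile normalization. With the mean over probes RPS24 was 0.0167 and RPS19 −0.0183. With single arrays left out NSDHL ranged from −0.0442 to 0.0115, UNG from −0.0152 to 0.1067, CKS2 from −0.0772 to 0.280, RPS19 from −0.0379 to 0.0453, MKI67 from −0.1416 to 0.0787 and MAP3K5 from −0.0568 to 0.0642. The cause was not tested. A slide block was not run, since there was 1 slide.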

Other observations

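The test on RNA without a poly(A) tail was chosen after the result was seen; the trend values without control replicate 1 and the trend counts of list members also come from tests added later, and the genes named here were chosen after their values were seen.

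Some genes of squamous and basal epithelium besides SPRR1B and SPRR3 passed lower with fucoidan when limma used the intensity trend. The keratin genes KRT6A, KRT14 and KRT17 stood at −0.72 ± 0.06, −0.57 ± 0.04 and −0.59 ± 0.05 (SE; adjusted p = 0.0106, 0.00601 and 0.00809 with the trend), the calcium-binding S100A2 at −0.52 (adjusted p = 0.00162), the serine protease KLK6 at −0.54 (adjusted p = 0.00251) and the serpin SERPINB5 at −0.38 (adjusted p = 0.00601). With the mean over probes KRT14 stood at −0.25. Other keratin genes of the same epithelia did not pass, with KRT5 at 0.10, KRT15 at −0.068, KRT6B at −0.076, KRT6C at −0.046 and KRT16 at −0.22. SPINK5, an inhibitor of such proteases, was higher, at 0.46 ± 0.06 (adjusted p = 0.00809), and stood at 0.27 with the mean over probes. IGFBP1, a binding protein of insulin-like growth factors, and DEFB4A, an epithelial defensin, were lower, at −0.63 and −0.56 (adjusted p = 0.00225 and 0.00251). The alcohol dehydrogenase genes ADH1A and ADH1C were higher, at 0.37 and 0.33 (adjusted p = 0.0431 and 0.00809). Of transcripts detected in 1 group only, CMTM2 and LIN7A were at least 4.99-fold and 5.86-fold lower, and ENO4 was at least 4.46-fold higher (adjusted p = 0.00251, 0.00601 and 0.00251 with the trend). Normexp correction, whose offset shrinks the differences of dim genes by construction, brought the difference in CMTM2 to −0.88 and in ENO4 to 0.69 at the smallest.

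A hypothesis was that SPRR1B and SPRR3 belong to a wider fall of squamous differentiation genes. A list of 80 such genes was written from background knowledge, and 47 were tested after 1 gene named by the rule was left out. KRT14, KRT17, S100A2, KLK6 and SPINK5, given above for their values, stayed in the list. The test is therefore not separate from those genes, and none was run without them. Of these 33 were lower, by a median of −0.080 (95% interval −0.164 to −0.032), with both fucoidan arrays below both control arrays in 25 and above in 9 (camera p = 0.000647, and p = 0.110 with an estimated correlation). The other splits of the arrays into pairs gave 0.759 and 0.716 as the p of camera in limma. Those splits put a control and a fucoidan array on each side, so a difference between the groups cancels and a high p was likely in advance. With the trend 6 of the 47, namely KRT14, KRT17, S100A2, KLK6, SPRR1A and EMP1, passed lower and 1, SPINK5, higher. Other SPRR genes in the list were mixed. SPRR1A stood at −0.23 and SPRR2D at −0.063, against 0.060 for SPRR2A, 0.042 for SPRR2F and 0.016 for SPRR2E. The test thus shows a shift of the list median, not a fall of every squamous gene. That shift was found and tested on the same arrays and may follow array position as well as fucoidan.

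The histone, mitosis and DNA replication genes, 125 in all, were lower by a median of −0.080 (95% interval −0.103 to −0.068). A gradient along the slide would repeat about this sign from position to position within a group, but the median step between the arrays of a group was 0.00627 (−0.0026 to 0.019). Taking off the median of the 200 genes nearest in signal left −0.0666 (−0.0783 to −0.0512), and of the 200 nearest in probe GC content −0.0703 (−0.0848 to −0.0538), so neither trend accounts for the whole shift. A response of cycling cells to fucoidan and a step between array pairs that is no gradient stay open. With 3 splits of the 4 arrays chance cannot be tested: 1 split, the real one, gave 9 lists, and the highest other gave 0.

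For the histone part, a lower yield of RNA without a poly(A) tail could be a further source, since replication-dependent histone transcripts lack one. Small non-coding RNAs without a tail, 243 in all, had a median of −0.0615 (−0.0859 to −0.0421), with both fucoidan arrays below both control arrays in 55 and above in 28, and did not pass camera in limma (p = 0.0574, and p = 0.734 with an estimated correlation). Against the median of −0.155 of the histone list theirs was too close to the bound set for the test to decide. RN7SK, RMRP, SNORA22, SNORA16A, SNORA16B and SNORA2C passed lower with the trend and 0 passed higher. However, the median step within the control and the fucoidan pair was −0.137 and −0.0892, more than the difference between the groups. Replication histone genes outside the list, 39 in all, were lower by a median of −0.127 (−0.151 to −0.0948; camera p = 4.59e-10, and p = 0.0946 with an estimated correlation). Of 8 histone genes whose transcripts carry a tail, 4 were lower, with a median of −0.030 (−0.102 to 0.032). The mitosis genes, whose transcripts carry tails, were lower by −0.073, which such a yield would not produce.

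The cholesterol synthesis genes were higher by a median of 0.068 (0.042 to 0.1496 over 26 genes). After taking off the nearest genes in signal the median was 0.0866 (0.056 to 0.170), and in probe GC content 0.0894 (0.0527 to 0.143), which argues against both as the whole source. A gradient along the slide cannot be told apart from fucoidan here: the mean step within groups was 0.0309 (0.0014 to 0.0671), from −0.0025 between the control arrays and 0.062 between the fucoidan arrays. A response of sterol synthesis to fucoidan also stays open and was not tested further.

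On the first control array 80 dim genes stood at least 2-fold above the other 3 arrays, against 14, 20 and 12 on the other arrays. Of their spots 21.2% had another such spot within 3 rows and 3 columns, against 0% to 15.0% in 100 random draws of spots of like signal, which is consistent with a local defect of that array for part of them. For the 5 genes with another probe the median excess of that probe was 0.0645 (−0.252 to 0.605), against 2.38 for the probe used, which are too few to tell whether the culture differed. Of the 80 genes 3 were among the trend calls, and without this array the trend called 72 genes higher and 138 lower.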
